A study of Homo sapiens with 9 samples.

How the data were processed

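RNA abundance was measured in 3 cultured human hepatocellular carcinoma cell lines, MHCC97L, Huh7 and HCCLM3, with 3 arrays per line and 9 arrays in all. Per the labels, all lines grew in the same serum-supplemented medium, total RNA was extracted with TRIzol, checked for integrity, column-purified and treated with DNase, and amplified and labelled with Cy3 by a one-colour low-input kit. The labels call the arrays of a line biological replicates without saying that they came from separate cultures, and the sample codes of MHCC97L replicates 2 and 3 differ only in a closing A or B. The p-values therefore measure the spread between these arrays, part of which may be technical.

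Each scanner file held 1 array of 180880 spots, of which 175906 were noncontrol probes and 4974 were control spots. Per the file headers, spot intensity had been extracted with Agilent Feature Extraction 10.7.1.1, which subtracted the background and removed spatial trends within the array. The submitters' processing notes name Agilent Feature Extraction 10.7. These intensity values were not scaled between arrays before they were deposited. The deposited flags (other values of 0 or 1) mark, per the file headers, spots well above background, saturated spots and outlier spots. The authors' series matrix held log2 values, and its columns shared a median of 3.447 on every array. Set against the scanner values of the same array, each column had a Pearson correlation across probes of at least 0.998 with the log2 signal, so the scale and direction were settled, and the equal sets of values in all columns show that the authors had quantile normalized them. The software used for that step is not given in the sources used here. The grid was designed on genome build hg19, per the file headers.

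All 175906 noncontrol probes carried their own probe ID in the columns for gene name and systematic name, an unknown description and an unmapped position. None of these names matched a symbol, synonym or transcript of the RefSeq gene table, and none of the 1015 symbols in the 21 gene lists fixed before the data were examined matched a noncontrol probe. The planned tests of gene lists, of non-coding transcripts and of chromosomes were therefore not run, and neither was the mean over the probes of a gene. Results are given per probe, by probe ID and sequence, for 3 series of IDs: 116154 probes named pl, 50683 named agiseq and 9069 named CUST. What distinguishes the series is not stated in the files, and probes were assigned no gene. The probes were 60 bases long, with 173505 distinct sequences.

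For the main setting, log2 of the processed signal was reduced by the array's 75th percentile over noncontrol probes. Control spots and outlier-flagged spots (49 to 93 per array) were left out. No noncontrol spot was saturated. Probes well above background on all 3 arrays of at least 1 line were tested, 71937 in all, after 37 more had been removed because every array of a line was flagged. One limma model with a mean per line was fitted to all 9 arrays with 6 residual degrees of freedom (limma 3.58.1, R 4.3.3), with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment within each comparison. A probe was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. All adjusted p values in the report come from limma.

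The rule for named items, set before the data were examined, took the 6 called genes with the largest rise and the 6 with the largest fall whose 3 and 3 values did not overlap. After the data were seen it was cut to 2 probes higher and 2 lower per comparison, because no gene was named, and to probes well above background on all 6 arrays, because values near background have no order. Its parts on gene lists, non-coding transcripts and genes named in advance could not be applied. Where a probe was not well above background on any array of a line, the fold was given as a lower bound. The bound set the brighter line's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

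The fit was tested on simulated data for each comparison, with the means and spreads of 71974 probes and 200 probes changed by known amounts. For MHCC97L minus Huh7, 50% of the probes changed by 1.5 on the log2 scale, 66% of those changed by 2, 88% of those changed by 3 and 100% of those changed by 4 were called in the right direction. For HCCLM3 minus Huh7 these shares were 46%, 78%, 94% and 94%, and for HCCLM3 minus MHCC97L 54%, 50%, 80% and 92%. Among unchanged probes 7, 8 and 5 were called. Each size had 50 probes per comparison. The noise was drawn independently per probe, without slide or array effects. Far fewer probes were changed than were called in any comparison of the data, and the adjustment is stricter when few probes change. These shares therefore do not give the sensitivity of the real fit.

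The arrays lay on 3 slides. The first slide held MHCC97L replicate 1 and all Huh7 arrays, the second held MHCC97L replicates 2 and 3 with HCCLM3 replicates 1 and 3, and the third held HCCLM3 replicate 2. Huh7 and HCCLM3 shared no slide. Alternatives fixed before the data were examined were scaling by the median or by the 75th percentile of probes detected on all arrays, quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the series matrix, no filter and a stricter filter on dim probes, a fit of the compared lines alone, the replicate number as a block, slide as a fixed or random block and within a slide, an intensity trend with robust spread, array weights, other thresholds, and the removal of each array in turn. Added after the data were seen were a lowess correction on probe GC content, averaging of identical sequences, MHCC97L by replicate 1 alone, MHCC97L with replicates 2 and 3 averaged, and removal of probes that differed within MHCC97L.

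Probes were taken as overlapping when they shared at least 25 consecutive bases on one strand, and as an opposite-strand pair when one shared at least 25 bases with the reverse complement of the other. Each probe entered only 1 opposite-strand pair, and identical sequences were counted once. Permutation tests on sequences used 100000 resamples and were tested on simulated data first. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the figures.

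The share of noncontrol probes well above background, the arrays' equivalent of depth, ran from 37.1% to 46.7%. Negative control spots were above background in 0.17% to 1.33% of cases. Precision was limited by the number of arrays.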

Results

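The series compared the RNA of MHCC97L with that of Huh7 and HCCLM3 on a one-colour array for non-coding RNA profiling. Huh7 is a well-differentiated hepatocellular carcinoma line. MHCC97L is a hepatocellular carcinoma line of low metastatic potential, and HCCLM3 is a highly metastatic line of the same MHCC97 family. Each line was measured on 3 arrays. Per array, 37.1% to 46.7% of the noncontrol probes were well above background. On all 3 arrays of a line, 64085 probes were well above background in MHCC97L, 59964 in Huh7 and 63167 in HCCLM3. Probes of the agiseq series were detected most often, with a mean of 62.8% above background per array, against 44.7% for the CUST series and 32.0% for the pl series. The name columns of the files repeat the probe ID, so the items below are probes, given with their sequence and without a gene.

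Arrays of one line resembled each other more than arrays of different lines. Across the 71937 tested probes, Pearson's r between arrays was 0.982 to 0.991 within MHCC97L, 0.958 to 0.980 within Huh7 and 0.975 to 0.983 within HCCLM3. Between HCCLM3 and MHCC97L the median r was 0.967, and between Huh7 and either of them it was 0.842. These correlations run across probes, which are not independent replicates. The first principal component held 74.1% of the variance and set Huh7 apart from both other lines, and the second held 8.7% and set MHCC97L apart from HCCLM3. The median SD of a probe over the 3 arrays was 0.20 on the log2 scale in MHCC97L, 0.29 in Huh7 and 0.30 in HCCLM3.

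**Figure D1:**
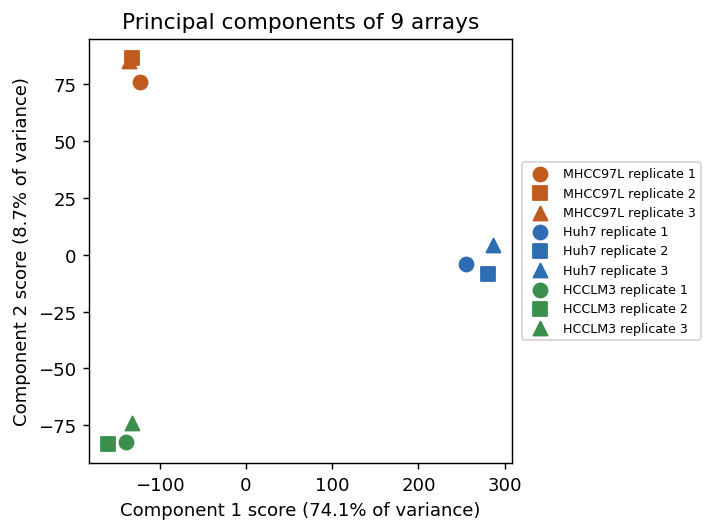
Scores of the 9 arrays on the first component (horizontal axis, 74.1% of variance) and the second (vertical axis, 8.7%), from scaled log2 signals of the tested probes; colour gives the line and shape the replicate number. Huh7 lies at 255.2 to 286.0 on the first axis and the other lines below 0, while MHCC97L lies at 76.1 to 86.6 and HCCLM3 at -83.3 to -73.9 on the second.

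MHCC97L replicates 2 and 3 were the most alike of all pairs, at r = 0.991. The labels call them separate biological replicates, yet their sample codes differ only in a closing A or B, while every other array has a code of its own. For 1017 sequences printed as more than 1 probe, the median absolute log2 difference between both spots of a sequence on one array was 0.13 in replicate 2 and 0.12 in replicate 3. Between replicates 2 and 3 the same sequences differed by a median of 0.15, against 0.26 to 0.28 between replicate 1 and either of them. The differences between replicates 2 and 3 recurred at both spots of a sequence with r = 0.34 across sequences, so they exceeded spot noise, which separate labelling of one RNA could also bring about. All 3 arrays were kept as replicates, as the labels give them. If both came from 1 culture, MHCC97L had 2 independent samples and its p-values are too small; with the pair averaged, 17579 probes were called between MHCC97L and Huh7 and 1146 between HCCLM3 and MHCC97L, against 19190 and 1962.

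MHCC97L and Huh7 differed at 26.7% of the probes that could be tested. At 9947 probes the signal was higher in MHCC97L and at 9243 it was lower, with a median absolute log2 difference of 1.89 among the 19190 called. Normexp background correction with quantile normalization called 10179, and a filter for probes above background on all 9 arrays 10300 of 52942. At least 16-fold differences, taken as fitted, were seen at 1175 probes higher and 1305 lower in MHCC97L. Of the pl series, 20.1% of tested probes were called, against 32.9% of the agiseq series and 33.5% of the CUST series. Calls of the pl series were higher in MHCC97L in 56.7% of cases, those of agiseq in 49.2% and those of CUST in 47.4%.

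Among probes well above background on all 6 arrays, agiseq45720 (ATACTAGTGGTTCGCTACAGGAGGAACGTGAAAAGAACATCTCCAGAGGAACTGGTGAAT) rose most from Huh7 to MHCC97L. Relative to the array's 75th percentile it stood at 8.82 ± 0.40 in MHCC97L and -0.88 ± 1.15 in Huh7 (log2, SD, n = 3 each), a log2 difference of 9.70 (SE 0.49, limma adjusted p = 6.56e-07). Next came agiseq39331 (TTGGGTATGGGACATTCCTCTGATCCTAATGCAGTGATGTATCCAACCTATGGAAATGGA), at 9.39 ± 0.23 against -0.23 ± 0.22, or 790-fold higher (limma adjusted p = 1.9e-08). Among probes so detected, the strongest falls were at agiseq27358 (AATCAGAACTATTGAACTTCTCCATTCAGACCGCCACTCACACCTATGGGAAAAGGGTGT) and pl019021 (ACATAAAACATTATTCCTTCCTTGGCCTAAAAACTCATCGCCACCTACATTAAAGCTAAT). Probe agiseq27358 stood at -0.14 ± 0.46 in MHCC97L and 10.67 ± 0.27 in Huh7, a log2 difference of -10.81 (SE 0.31, limma adjusted p = 3.67e-08). Probe pl019021 stood at 0.00 ± 0.33 against 10.76 ± 0.27, a log2 difference of -10.76 (SE 0.28, limma adjusted p = 2.43e-08).

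Many differences ran between detection and background. On all 3 MHCC97L arrays and no Huh7 array, 2839 probes were well above background, and 2418 of them were called. The reverse held for 2231 probes, of which 2182 were called. The called probes seen in Huh7 and not in MHCC97L were at least 4.07-fold higher in Huh7 at the median, and 405 were at least 16-fold higher. The called probes seen in MHCC97L and not in Huh7 were at least 2.45-fold higher in MHCC97L at the median, with 221 at least 16-fold higher.

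Overlapping probes moved together between MHCC97L and Huh7. Of 2155 groups of tested probes that shared sequence on one strand, 896 held a call, 696 had every tested member called in one direction and 2 had members called in both directions. Across 3389 overlapping pairs, the log2 differences correlated at r = 0.956, across probes that are not independent. Of the 19190 called probes, 18948 had no overlap between the 3 and 3 values, which the thresholds favour. This was true of 49.3% of all tested probes. Chance gives 10% for an unfiltered probe, but the detection filter and any scaling offset can raise that share. With each array's median in place of its 75th percentile, the median difference of all tested probes moved to 0.37 and 69.0% of calls were higher in MHCC97L, against 51.8%. That share was 39.9% with no filter on dim probes and 49.5% with the 75th percentile of probes detected on all arrays, so which direction prevailed was not settled. Within the slide that held both lines, 8696 probes were called from 1 MHCC97L array and 3 Huh7 arrays, with all of the spread taken from Huh7, and with slide as a fixed block 14719.

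HCCLM3 also differed from Huh7 widely, at 27.4% of the tested probes. The signal was higher in HCCLM3 at 10461 probes and lower at 9252, 19713 in all, with a median absolute log2 difference of 1.90. Normexp correction called 10530 and the filter on all 9 arrays 10739. At least 16-fold differences, as fitted, were found at 1199 probes higher and 1465 lower in HCCLM3. The pl series was called at 20.5% of its tested probes, agiseq at 34.0% and CUST at 33.7%. Calls were higher in HCCLM3 for 59.8% of the pl series, 49.5% of agiseq and 46.2% of CUST.

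Among probes well above background on all 6 arrays, the same 4 probes had the largest rises and falls between Huh7 and HCCLM3. Probe agiseq45720 stood at 9.86 ± 0.22 in HCCLM3 against -0.88 ± 1.15 in Huh7 (log2, SD, n = 3 each), a log2 difference of 10.74 (SE 0.49, limma adjusted p = 3.15e-07). Probe agiseq39331 was 744-fold higher (limma adjusted p = 1.72e-08). Probe pl019021 had a log2 difference of -11.26 (SE 0.28, limma adjusted p = 1.77e-08) and agiseq27358 one of -11.05 (SE 0.31, limma adjusted p = 2.82e-08). Both stood below the array's 75th percentile in HCCLM3, at -0.50 ± 0.47 and -0.38 ± 0.48.

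On all 3 HCCLM3 arrays and no Huh7 array, 2647 probes were well above background and 2303 of them were called. The reverse held for 2715 probes, 2635 of them called, and these were at least 3.92-fold higher in Huh7 at the median. Of the overlapping probe groups, 902 held a call and 704 had every tested member called in one direction. HCCLM3 and Huh7 shared no slide, and with slide as a fixed block, estimated through MHCC97L, 9674 probes were called. With scaling by the median, 62.9% of calls were higher in HCCLM3, against 53.1%, with no filter 46.1% and with the 75th percentile of detected probes 47.5%, and the median difference of all tested probes moved to 0.24.

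**Figure D2:**
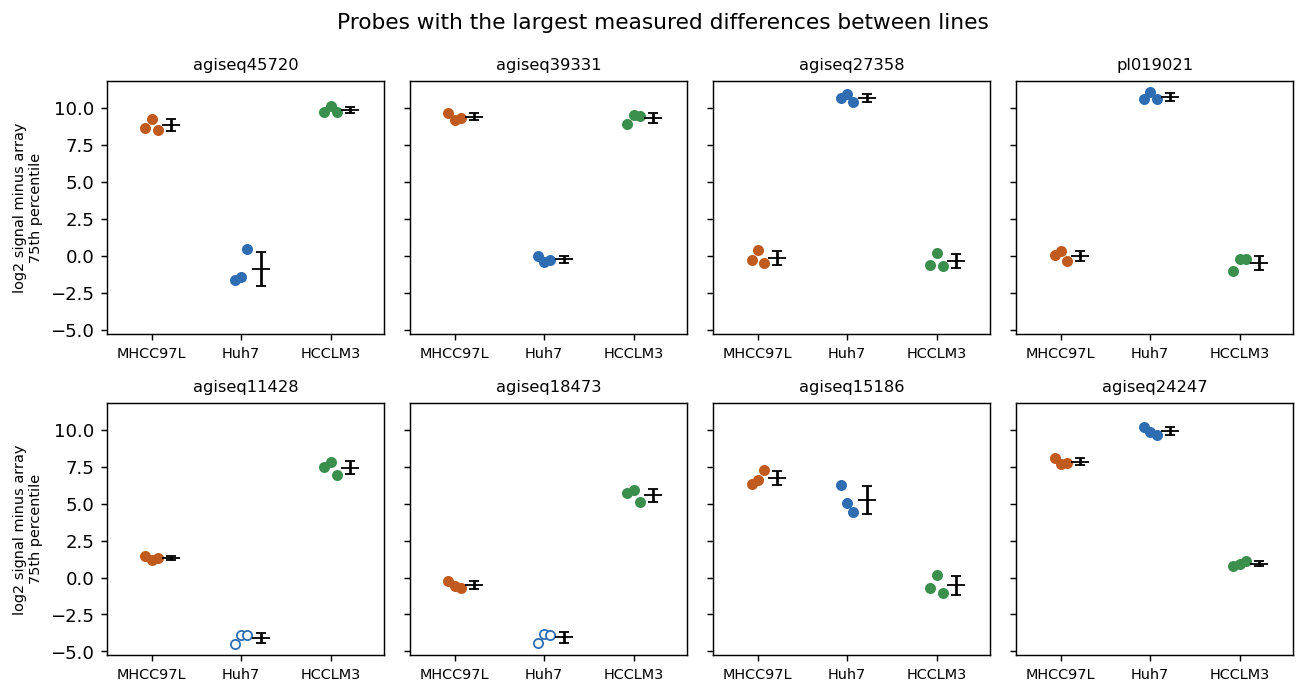
Scaled log2 signal (vertical axis, minus the array's 75th percentile) of the 8 named probes on each array, by line; points are arrays, open points were not well above background, and bars give the mean and SD of 3 arrays. Probes agiseq45720 and agiseq39331 stand above 8.5 in MHCC97L and HCCLM3 and below 0.5 in Huh7, and agiseq27358 and pl019021 show the opposite order.

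Most probes that separated one line from Huh7 separated the other too. In the same direction, 15604 probes were called in both comparisons (8332 with normexp correction, 8136 with the filter on all 9 arrays and 8509 with slide as a fixed block), 8037 lower in Huh7 than in both lines and 7567 higher, and 62 were called in opposite directions. Scaling by the median gave 11231 lower and 5906 higher, and the 75th percentile of detected probes 7404 lower and 8084 higher. Independent lists of these sizes would share 1446 and 1189. The log2 differences correlated at r = 0.924, across probes that are not independent, and 83.6% of probes had the same sign. In 20 simulations, all 9 arrays were drawn around the Huh7 means with no difference between groups, and both comparisons shared the Huh7 group. The mean r was 0.501 and the same-sign share 66.7%. Sharing a group of equal size sets both values in advance when nothing differs. They are a baseline for no differences and do not test a common pattern. No probe was called in both, but groups without differences yield few calls at all, so that count gives no support. The simulations do not show how far the shared arrays raise the overlap when many probes differ. The covariance was 2.26 against a simulated 0.062, a difference of 2.19. The 3 Huh7 arrays are too few to split, so part of the excess over independent lists may come from the shared arrays.

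HCCLM3 and MHCC97L, the lines of one family, differed at far fewer probes. At 810 probes the signal was higher in HCCLM3 and at 1152 it was lower, together 2.7% of the tested probes. The median absolute log2 difference of the 1962 called was 1.99. The agiseq series held 1205 of the calls, 33.4% of them higher in HCCLM3. The pl series held 605 calls, 54.4% of them higher, and the CUST series 152, 51.3% of them higher.

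Probe agiseq11428 (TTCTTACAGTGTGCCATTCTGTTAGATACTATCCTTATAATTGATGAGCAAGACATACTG) rose most from MHCC97L to HCCLM3 among probes well above background on all 6 arrays of both lines. It stood at 7.43 ± 0.44 in HCCLM3 and 1.31 ± 0.11 in MHCC97L (log2, SD, n = 3 each), a log2 difference of 6.11 (SE 0.26, limma adjusted p = 7.46e-06), and was not well above background on any Huh7 array. Probe agiseq18473 (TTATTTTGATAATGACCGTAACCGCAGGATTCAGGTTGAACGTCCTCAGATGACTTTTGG) was 67.8-fold higher in HCCLM3 (limma adjusted p = 7.94e-06), its 1 overlapping tested probe was called the same way, and it too was not well above background in Huh7. Probe agiseq15186 (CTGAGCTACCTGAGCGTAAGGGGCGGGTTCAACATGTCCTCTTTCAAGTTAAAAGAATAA) fell most, from 6.73 ± 0.49 in MHCC97L to -0.53 ± 0.65 in HCCLM3, a log2 difference of -7.26 (SE 0.49, limma adjusted p = 7.38e-05), and stood at 5.25 ± 0.93 in Huh7. Probe agiseq24247 (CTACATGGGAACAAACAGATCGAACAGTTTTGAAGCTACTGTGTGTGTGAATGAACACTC) fell from 7.84 ± 0.25 to 0.92 ± 0.17, a log2 difference of -6.91 (SE 0.21, limma adjusted p = 2.27e-06), and stood at 9.89 ± 0.28 in Huh7.

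On all 3 HCCLM3 arrays and no MHCC97L array, 314 probes were well above background, and 216 were called. The reverse held for 742 probes, of which 354 were called. Of the overlapping probe groups, 109 held a call, 69 had every tested member called in one direction and none had members called in both directions. All 1962 called probes had separate 3 and 3 values, which the thresholds favour, as did 21.3% of the tested probes. Chance gives 10% for an unfiltered probe, but the detection filter and any scaling offset can raise that share.

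The number called between HCCLM3 and MHCC97L depended on single arrays and on the setting. It rose to 5127 with array weights and fell to 831 with the filter on all 9 arrays, 991 with normexp correction, 969 at an adjusted p under 0.01, 1245 with no filter and 558 with MHCC97L by replicate 1 alone. It was 1178 without MHCC97L replicate 2, 1126 without MHCC97L replicate 3 and 1235 without HCCLM3 replicate 1, and 1146 with MHCC97L replicates 2 and 3 averaged into 1 sample. Within the slide that held 2 arrays of each line 1444 probes were called, and with slide as a fixed block 1000. With scaling by the median, 29.6% of calls were higher in HCCLM3, against 41.3%, and the median difference of all tested probes moved to -0.11. Without MHCC97L replicate 1 that share was 48.2%, and without HCCLM3 replicate 3 it was 46.0%, so the excess of lower calls rested in part on single arrays.

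Each line also stood apart from both others at some probes. Huh7 was higher than both at 7567 probes and lower at 8037, an order that turned to 8084 and 7404 with the 75th percentile of detected probes and widened to 5906 and 11231 with the median. MHCC97L was higher than both at 529 and lower at 242, and HCCLM3 was higher than both at 547 and lower at 593. The MHCC97L counts fell to 294 and 144 without MHCC97L replicate 3, and the HCCLM3 counts to 327 and 389. Slide as a fixed block gave 234 and 114 for MHCC97L and 267 and 281 for HCCLM3. Normexp correction gave 299 and 74 for MHCC97L and 278 and 249 for HCCLM3. With array weights they rose to 1519 and 836 for MHCC97L and 1044 and 1354 for HCCLM3. Each line's excess of one direction rested in part on single arrays, since the MHCC97L counts were 330 and 292 without MHCC97L replicate 1, and the HCCLM3 counts 534 and 512 without HCCLM3 replicate 3. The HCCLM3 order also depended on the processing. It turned with normexp correction and with no filter (389 and 384), and held with the filter on all 9 arrays (188 and 274).

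The only probes on the array that the files name by human gene were control probes for GAPDH and PGK1, both enzymes of glycolysis, each near the 3' and 5' end of the transcript. Neither gene passed the test in any comparison, with limma adjusted p from 0.532 to 0.973. At its 3' probe, GAPDH stood at 11.73 ± 0.25 in MHCC97L, 11.69 ± 0.36 in Huh7 and 11.86 ± 0.36 in HCCLM3 (log2, SD, n = 3 each). At its 3' probe, PGK1 stood at 10.80 ± 0.23, 10.92 ± 0.08 and 11.03 ± 0.38.

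**Figure D3:**
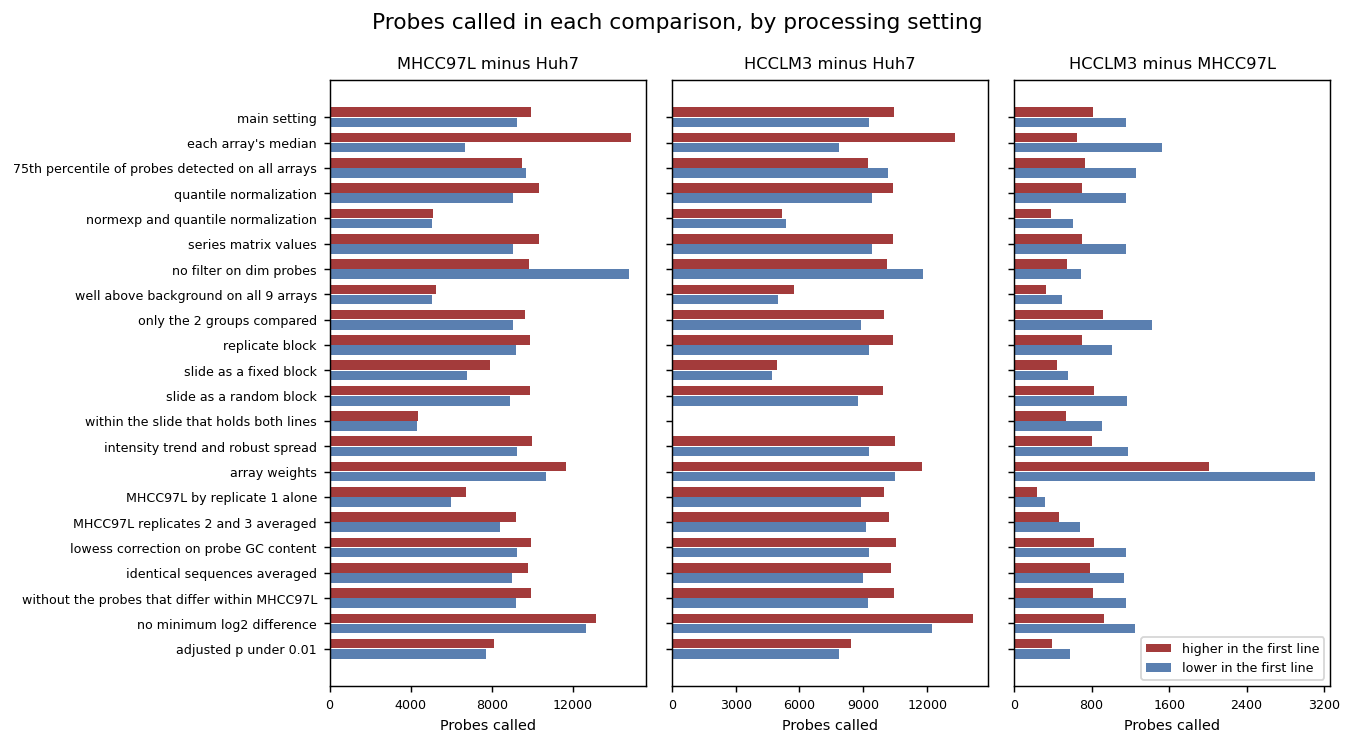
Number of probes called (horizontal axis) in each comparison, higher (red) or lower (blue) in the line named first, for the main setting and each alternative other than the removal of single arrays. With the main setting 19190, 19713 and 1962 probes were called, and scaling by the median raised the share higher than Huh7 to 69.0% for MHCC97L and 62.9% for HCCLM3; no slide held HCCLM3 and Huh7 together.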

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

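The following signals came from control probes, which no comparison used, and they were looked at after the main results had been seen. A set of 6 control probes named for mouse, rat or for the ERCC and ETG control families had every spot well above background on all 9 arrays. Of the 12 ERCC probes 1 did so, ERCC-00062_278, at a mean log2 signal of 9.48. Of the 13 ETG probes 1 did so, ETG05_36762, at 5.85. Among the mouse and rat probes, the means were 9.14 for Mouse-GAPDH_3, 10.03 for Mouse-PGK1_5, 12.24 for Rat-GAPDH_5 and 10.63 for Rat-PGK1_5. The negative control probe had a mean of 1.82 over the arrays. The labels name no added ERCC RNA, and no explanation was tested for these signals.

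The probe ETG09_35454 differed between arrays of one line. Its log2 signal was 3.97 in MHCC97L replicate 1, with 57.5% of spots above background, and 2.06 and 1.95 in replicates 2 and 3, with none. In Huh7 it was 4.71 to 5.46, and in HCCLM3 3.67 to 6.15.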

How the results depend on the processing

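The 8 named probes kept their direction and stayed called under every alternative that could be run for them, 318 values in all. They were picked from these data for their large differences, so this says little about other calls. The cause of the shifts in the counts below was not tested unless stated. For MHCC97L minus Huh7, HCCLM3 minus Huh7 and HCCLM3 minus MHCC97L, normexp correction with quantile normalization called 10179, 10530 and 991 probes, and probes above background on all 9 arrays, with 52942 tested, gave 10300, 10739 and 831. With slide as a fixed block the counts were 9674 for HCCLM3 minus Huh7 and 1000 for HCCLM3 minus MHCC97L, and within 1 slide 8696 for MHCC97L minus Huh7, with 1 MHCC97L array and the spread from Huh7 alone. HCCLM3 minus MHCC97L had 1245 calls with no filter, 5127 with array weights and 969 at an adjusted p under 0.01. Settings added after the data were seen gave 12710 for MHCC97L minus Huh7 and 558 for HCCLM3 minus MHCC97L with MHCC97L by replicate 1 alone, which takes the spread from the other lines, and 1146 for the latter with replicates 2 and 3 averaged. Removing 1 array at a time gave 17322 to 20926, 18273 to 21377 and 1126 to 2357 calls. Of 30, 29 and 30 alternatives, 26, 26 and 19 kept the count within 1.5 times. The overlap of both comparisons with Huh7 was 8332 with normexp, 8136 with the strict filter, 8509 with slide as a fixed block, and 14318 to 17259 without 1 array.

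The replicate number as a block gave 19133, 19657 and 1710 calls. Deviations of same-numbered arrays correlated at -0.11 to 0.23 over 9 pairs, 1 of them over 0.1, and 3 of 9 arrays matched their own number best, so the numbers were not taken to pair the arrays. Control probes for GAPDH and PGK1 stayed under the threshold but changed sign with scaling. With the median, PGK1 at 3' and 5' became 0.23 and 0.28 for MHCC97L minus Huh7, and GAPDH at 3' and 5' and PGK1 at 5' became -0.02, -0.10 and -0.03 for HCCLM3 minus MHCC97L. With the 75th percentile of detected probes, GAPDH at 3' became -0.01 for MHCC97L minus Huh7, PGK1 at 5' -0.06 for HCCLM3 minus Huh7 and GAPDH at 5' -0.01 for HCCLM3 minus MHCC97L. Gene lists, non-coding transcripts, chromosomes and the mean over a gene's probes were not run, for want of gene names. Probes near background limit the dim side of a fold to a bound.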

Other observations

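Some tests below were chosen only after the result was seen. These were of probes bright in a single MHCC97L array, of copying between strands and of brightness in opposite-strand pairs. The fit within 1 slide was fixed before the data were examined. Its call count was taken as a test of slide only after the result was seen. The correction for GC content was added after the data were seen. Probes on opposite strands of one sequence tended to differ between the lines in the same direction. Over 329 pairs of tested probes on opposite strands, log2 differences correlated at r = 0.533 for MHCC97L minus Huh7, 0.507 for HCCLM3 minus Huh7 and 0.488 for HCCLM3 minus MHCC97L, across pairs that are not independent. In the same order, normexp correction gave 0.386, 0.369 and 0.429, and the filter on all 9 arrays 0.418, 0.396 and 0.589. For HCCLM3 minus MHCC97L, slide as a fixed block gave 0.405. Of 80 alternative values, 70 stayed within 1 SD of r over resampled pairs. Both probes were called in 53 pairs for MHCC97L minus Huh7, 48 of them in the same direction, and in 47 pairs for HCCLM3 minus Huh7, 41 of them in the same direction. In no pair were both called for HCCLM3 minus MHCC97L. Pairs with only 1 strand called were more frequent, at 71, 77 and 10 in the 3 comparisons. Detection separated Huh7 most: 1778 probes were well above background on all 3 Huh7 arrays and no other, and 1816 on all 6 other arrays and no Huh7 array. For MHCC97L these counts were 271 and 56, and for HCCLM3 174 and 256.

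The agreement of opposite strands was weighed against 2 technical explanations. Pairs drawn at random and matched on mean signal had a mean r of 0.009 to 0.027 and never reached the observed value in any comparison (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give), which argues against a signal that follows probe brightness. A shift common to all probes would not move r, so it was not tested. If labelling had copied one strand into the other in every pair, opposite directions would be rare, but of 61 distinct pairs with both probes called in at least 1 comparison, 8 (13.1%, 95% Wilson interval 6.8 to 23.8) went opposite ways, in comparisons that share arrays. Copying in part of the pairs and regulation of both strands at one locus stay open, and the latter was not tested.

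The 1962 calls between HCCLM3 and MHCC97L were weighed against slide, GC content and array brightness. From the 4 arrays of the slide that held 2 of each line, 1444 of all tested probes were called. Differences between slides cannot produce these, which argues against slide as the whole cause. The 2 other splits called 0, but each mixed the lines within a group, which widens the spread, so they add no support. On this slide MHCC97L lay at positions 1 and 2 and HCCLM3 at positions 3 and 4, so line and position cannot be told apart. Only 51.2% of the 1962 were called again within that slide and 42.8% with slide as a fixed block. Fewer arrays or residual degrees of freedom can also cost calls, so these losses do not show a slide effect, which stays open for the other calls. A lowess correction on GC content kept 98.0% of the calls and quantile normalization 90.5% (95% Wilson interval 89.1 to 91.7). The interval treats probes as independent, which they are not. GC content or brightness as the cause called for a loss of most. Both steps remove only trends across an array, and the main setting was already scaled. These values therefore speak only to such trends, and effects on single probes stay open. Normexp correction, also followed by quantile normalization, kept only 43.6%. The filter on all 9 arrays, which tested fewer probes, kept 41.4%. It could not test the 216 and 354 called probes seen on all arrays of one line and none of the other. Of its 831 calls, 813 were among the 1962 in the same direction. The cause of the other losses was not tested, so the 90.5% holds for quantile normalization without background correction. A difference between the lines remains open, as does a difference between single cultures, since MHCC97L replicates 2 and 3 may come from 1 culture.

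In MHCC97L, 664 probes were bright in replicate 1 and not above background in replicates 2 and 3. Other arrays had 464 to 1139 such probes, so replicate 1 does not stand apart in this number. Huh7 arrays, on the slide of replicate 1, had 12.8% to 22.3% of these probes above background. This argues against a gain of most of these probes on every array of that slide. Each Huh7 array stood above the HCCLM3 arrays on the other slides (10.2% to 12.2%). A gain of part of the probes therefore stays open, as line and slide are confounded here. A loss on the slide of replicates 2 and 3 stays undecided, since HCCLM3 had 11.2% there and 11.9% on another slide. The most frequent word of 8 bases was shared by 10 of 652 sequences, against a median of 12 in random sets matched on GC content (permutation p = 0.967), so one labelled sequence that binds them all is not supported. Replicates 2 and 3 were both brighter than replicate 1, the dimmer of them by 0.43 on the log2 scale at the 75th percentile. This argues only against low brightness of these 2 arrays. The probes were defined in part by a log2 gap over 2 after scaling by that percentile. Brighter arrays widen this gap, so a part played by scaling stays open.

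Each comparison had 10 splits of its 6 arrays into 3 and 3, too few for a share under 0.05. For MHCC97L minus Huh7 the real split called 19190 probes and the highest other split 0, for HCCLM3 minus Huh7 19713 and 0, and for HCCLM3 minus MHCC97L 1962 and 0. In each comparison 1 of the 10 splits, the real one, gave as many. Every other split mixed the lines within a group, which widens the spread, so few calls were likely there.

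Some probes were bright on a single array of a line. For every array, most of them were above background on no array of the other lines. This held for 683 of 1139 in Huh7 replicate 1 and 424 of 659 in MHCC97L replicate 1. Of 1139 such probes in Huh7 replicate 1, 89 were above background on all 6 arrays of the other lines, and the latter count was 10 in Huh7 replicate 2 and 41 in Huh7 replicate 3. In MHCC97L replicate 1 it was 34 of 659, where outlier-flagged spots, kept in the 664 above, were left out. These 4 arrays shared the first slide, and on each of the 5 arrays of the other slides the count was 1 to 3. They include all Huh7 arrays, so line and slide are largely confounded here. For each Huh7 array, the Huh7 arrays that lacked its probes lay on the same slide. No explanation was tested for this pattern.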
